A study of Mus musculus with 9 samples.

How the data were processed

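Expression was measured by RNA sequencing in 9 libraries of mouse cells of strain C57BL, 5 of Lewis lung carcinoma (LLC) cells and 4 of bone-marrow-derived macrophages (BMDM), with total RNA taken by Trizol per the labels' protocols. Groups were taken from the titles and treatment labels, and each group held 1 library. GM-BMDM and M-BMDM are the labels' names for the 2 kinds of macrophage. The hours of tunicamycin, of medium conditioning and of culture in medium came from the labels and the series' design text. How the untreated LLC cells were fed was not given in the sources used here.

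Read counts per gene were deposited in 1 table for LLC and 1 for BMDM, and they were whole numbers in each cell tested (0 exceptions). FPKM values were deposited beside the counts, per the file headers. The deposited FPKM equalled the values recomputed from count, gene length and total count within 5.0e-07 for LLC and 4.9e-06 for BMDM, and were used for that check alone. The last column of the LLC table carried a line-end character in its quoted cells, which was stripped before reading. Cutadapt 1.15, HISAT2 and TopHat2 2.1.0 were used, per the submitters' processing notes, which give no role or order. The counter, its strand setting and the genome build were not given in the sources used here. Of 21894 LLC gene IDs shared with the GENCODE M21 annotation of GRCm38, 21681 (99.0%) had equal coordinates, and positions are printed for that build. The LLC table listed 21936 genes, and 22060 genes stood in that of BMDM, of which 21820 were in both. BMDM symbols were taken from the LLC table for those 21820 IDs and from GENCODE M21 for 226, and 14 had none. All lines named a gene.

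CPM values (reads scaled to a common library size) were computed here from the deposited counts, with TMM effective library sizes from edgeR per table, so levels were compared only within a table. Differences between 2 libraries are log2(CPM + 1) of the first minus the second, computed from the deposited counts. A gene counted as higher or lower from a log2 difference of 1. Genes entered with a mean of at least 1 CPM over the libraries of a table, 11190 for LLC and 11049 for BMDM. Folds are ratios of CPM without a pseudocount, computed from the deposited counts, with exact Clopper-Pearson intervals at 95%. Where a library had 0 counts the fold is given against a floor of 3 counts put in its place, which is not the limit of an interval. The 10 comparisons of 2 libraries carry no p-value.

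Gene lists numbered 30: ER chaperone and ERAD, PERK-ATF4 integrated stress response, NF-kB cytokines and chemokines, interferon-stimulated genes, MHC class I, MHC class II and dendritic cell, M-CSF macrophage, M1 and M2 polarization, secreted danger signals, glycolysis, hypoxia, cholesterol synthesis, mitosis, DNA replication, p53 and apoptosis, matrix and mesenchymal, matrix proteases and plasminogen, NRF2 antioxidant, cytosolic heat shock, immune checkpoint ligands, lysosome and autophagy, and mitochondrial mRNAs, and markers of macrophages, neutrophils, lymphocytes, mast cells with basophils and eosinophils, fibroblasts, erythroid cells and epithelium. Some genes are in more than 1 list. For lists with at least 3 members compared, the median log2 difference was set beside the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Of 254 list medians 133 lay outside the range of 95% of random lists. These ranges describe the libraries and are not tests.

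Additive fits used edgeR's quasi-likelihood test on counts with Benjamini-Hochberg adjustment at 0.05. The standard errors (SE) printed were derived from that test, as the absolute log2 fold change divided by the square root of its F statistic. The BMDM fit held kind and tunicamycin. The LLC fit held the kind of medium, its tunicamycin and medium against none. Each left 1 residual degree of freedom per gene, moderated over genes. The coefficient of variation was 11.5% in BMDM and 4.3% in LLC, and the small LLC value underlies its very small p-values. The prior degrees of freedom were 5.77 in BMDM and infinite in LLC, so that the quasi-likelihood spread of LLC genes came from the trend over genes and not from each gene. Calls of a list's members were also adjusted over the list alone, with no correction across lists. Correlations across genes used Pearson's r and Spearman's rho, and for the shared untreated library 100 sets of unchanged libraries were simulated.

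The text names, per comparison of 2 libraries, the 6 largest positive and 6 largest negative differences among genes with at least 5 CPM in either library and a symbol that is not predicted, clone-derived or pseudogene. It draws further on up to 4 members of each list with the largest absolute difference, 16 genes named in every comparison, and for the fits the 6 genes of lowest p per direction and list members that passed. Not all of these are printed. Other genes that are printed, such as those of the difference of responses, were chosen after their values were seen. The groups, comparisons, tests, lists, this rule and most alternatives were set before the data were examined. The difference of the 2 responses, the assumed dispersions and the fit without the untreated library were added later.

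The fits were tested on simulated data with 200 genes changed. All genes of a table were given the dispersion estimated in its own fit, 0.01321 for BMDM and 0.001835 for LLC. Each change was made equal in both kinds. The rates hold for these settings, and not for genes whose spread is larger or whose responses differ between kinds. With edgeR's quasi-likelihood test, 97% of 2-fold and 41% of 1.5-fold changes were found for the BMDM tunicamycin fit with 2.1% of calls false, and 97%, 51% and 5.2% for the BMDM kinds. For LLC the values were 96%, 89% and 7.5% for stressed medium, 94%, 86.9% and 4.3% for the kind of medium, and 91%, 83.7% and 2.3% for any medium. With DESeq2, 84%, 85%, 82%, 81% and 78% of 2-fold changes and 17%, 22.4%, 56%, 50.5% and 48% of 1.5-fold changes were found in the same order, with at most 0.9% of calls false. The pairs were simulated apart, with counting error alone and no dispersion, and with only the ER chaperone list changed. There 95.0% to 95.7% of intervals held the true ratio, which such intervals give by construction. Their coverage with a spread beyond counting error was not tested. The list, planted at a log2 difference of 1, was recovered at 0.99 to 1.01.

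Alternatives were DESeq2, its size factors, no filter or a mean of at least 5 CPM, a pseudocount of 0.1, intervals beyond 2-fold, fits with the factor of interest alone or without the untreated LLC library, unmatched random lists, and assumed dispersions of 0.01 and 0.04. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. With no strand information, genes that overlap another gene on the opposite strand are uncertain, as are members of families with near-identical copies. These include Cryab with Hspb2, H2-DMa with Brd2, Ogn with Cenpp, Adamts7 with Tbc1d2b and Cebpb with Tmem189.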

Results

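RNA was sequenced from 9 mouse cell cultures with 1 library per group. The macrophage part held 4 libraries of bone-marrow-derived macrophages (BMDM) of 2 kinds, named GM-BMDM and M-BMDM in the labels, untreated or after 4 h of tunicamycin. Tunicamycin blocks N-linked glycosylation of proteins and so causes folding stress in the endoplasmic reticulum (ER). The tumour part held 5 libraries of Lewis lung carcinoma (LLC) cells, a mouse tumour cell line. LLC cells were left untreated or were cultured for 24 h in medium that macrophages of either kind had conditioned for 16 h. The macrophages had been kept without tunicamycin or with tunicamycin for 12 h, and were washed before the fresh medium was added. Medium from tunicamycin-treated macrophages is called stressed medium here, and medium from macrophages kept without it is called unstressed medium.

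Assigned reads totalled 15020068 in untreated LLC cells, 15423518 with unstressed GM medium, 15291644 with unstressed M medium, 16027498 with stressed GM medium and 17128471 with stressed M medium. The totals were 42107553 in untreated GM-BMDM, 42751176 in GM-BMDM with tunicamycin, 37695079 in untreated M-BMDM and 39592377 in M-BMDM with tunicamycin. There were no replicates within any group. Folds between 2 libraries are therefore given with 95% intervals that cover counting error only, and reads are not independent molecules. Such a fold compares the 2 libraries and has no replicate check. The additive fits measure only the spread between these single libraries, since nothing in the labels says that they came from separate cultures.

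The first question was how the 2 kinds of macrophage differed before stress. Untreated GM-BMDM held far more RNA of Chil3, a secreted chitinase-like protein (1481-fold higher, 1174 to 1897), and of the arginine-degrading enzyme Arg1 (2447-fold, 1401 to 4737) than untreated M-BMDM. Fibronectin, Fn1, was 670-fold higher (528 to 865) and the protease inhibitor Spint1 was 378-fold higher (258 to 579). The matrix protein gene Ccn3 and the chemokine gene Ccl17 had 2 counts each in M-BMDM, and their ratios of 6892 and 5332 had lower bounds of 1908 and 1476. M-BMDM held more RNA of the lectin receptor Clec4a1 (150-fold, 114 to 202), the scavenger-receptor family member Cd5l (122-fold, 85.4 to 181), Gpr162 (117-fold, 83.9 to 168), the antiviral gene Ifit3 (64.5-fold, 53 to 79.2), the adhesion molecule Cadm1 (51.1-fold, 44.4 to 58.9) and the scavenger receptor Stab1 (40.2-fold, 38.4 to 42.2). In total 1371 genes were at least 2-fold higher and 776 at least 2-fold lower in GM-BMDM, of 11049 compared.

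The fixed gene lists separated the 2 kinds in several ways. All 30 interferon-stimulated genes were lower in GM-BMDM, 24 of them at least 2-fold, with a median log2 difference of -2.57. They included Irf7, a regulator of interferon genes (29.6-fold lower), and the chemokine Cxcl10 (51.9-fold lower). The M-CSF macrophage list had a median of -2.70, with 15 of 20 members at least 2-fold lower, among them the growth factor receptor Csf1r (5.51-fold), Adgre1, which encodes F4/80 (6.73-fold), the transcription factor Maf (14.3-fold) and Gas6 (21.2-fold). GM-BMDM were higher for mitosis genes (median 3.05, 19 of 20 at least 2-fold; Ccna2 24.9-fold), DNA replication genes (1.29, 16 of 21; Rrm2 18.3-fold), MHC class II and dendritic cell genes (1.86, 12 of 17; the integrin Itgax 96.7-fold), cholesterol synthesis (1.40, 18 of 23), M2 polarization genes (1.33, 9 of 13) and matrix proteases (3.35, 7 of 9; Mmp12 42.6-fold, 41.8 to 43.5). Among checkpoint ligands (median 1.09), Cd274, which encodes PD-L1, was 6.82-fold higher in GM-BMDM. The medians were -0.50 for M1 polarization, -0.35 for NF-kB cytokines and chemokines, -0.65 for MHC class I, -0.65 for NRF2 antioxidant genes, 0.85 for glycolysis, 1.49 for secreted danger signals, 1.05 for matrix genes, 0.19 for lysosome genes, 0.32 for heat shock, 0.34 for p53 genes, 0.09 for hypoxia and -0.28 for pan-macrophage markers.

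Markers of other blood cells moved with these groups. Of 13 neutrophil markers listed 7 were compared, and of 8 markers of mast cells, basophils and eosinophils 3 were compared. Of the 7 neutrophil markers, 6 were at least 2-fold higher in GM-BMDM (median 4.55), including S100a8 (36.2-fold), S100a9 (45.3-fold), Ngp (171-fold) and Mmp8 (32-fold). All 3 mast cell, basophil and eosinophil markers compared were higher (median 4.36), including Kit (45.7-fold) and Siglecf (152-fold). These 3 lay below 1 CPM in M-BMDM with and without tunicamycin, so they passed the minimum level only through GM-BMDM. The third, Cpa3, stood at 3.477 CPM in untreated GM-BMDM. The 6 mitochondrial mRNAs were higher with a median of 1.36, and mitochondrial mRNA made up 1.86% of counts in untreated GM-BMDM and 0.9% in untreated M-BMDM. The 10 most abundant genes took 14.0% and 12.7% of counts. The lymphocyte list had 1 member compared, Cd4, 20.5-fold lower in GM-BMDM (12.4 to 36.3). The epithelial list had 1, Cdh1, which rested on 1 count in M-BMDM (ratio 2738, with a lower bound of 491). No fibroblast or erythroid marker passed the minimum level in macrophages.

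A fit over all 4 macrophage libraries, with tunicamycin as an additive term, compared the 2 kinds. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2803 genes rose and 2765 fell in GM-BMDM relative to M-BMDM, and DESeq2 called 4588 of these 5568 genes as well. The genes of lowest p that rose were the ribonuclease Ear2 (log2 fold change 9.02 ± 0.20 SE), Spint1 (8.51 ± 0.17), the activin subunit Inhba (8.03 ± 0.18), the chemokine receptor Ccr1 (7.39 ± 0.16), Fstl1 (7.29 ± 0.16) and the growth factor receptor Met (6.25 ± 0.15). Those that fell were the adrenergic receptor Adra1a (-8.41 ± 0.24), Cd5l (-7.19 ± 0.20), Gpr162 (-7.11 ± 0.20), Ifit3 (-5.88 ± 0.15), Cadm1 (-5.60 ± 0.14) and Ifit2 (-4.93 ± 0.14). Each of these 12 had an adjusted p of 2.3e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

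All 30 interferon-stimulated genes fell in GM-BMDM in this fit, and all 20 mitosis genes rose. Cholesterol synthesis genes rose for 21 of 23, DNA replication genes for 19 of 21, MHC class II and dendritic cell genes for 15 of 17 with 1 that fell, and M2 polarization genes for 10 of 13 with 1 that fell. Of 20 M-CSF macrophage genes 16 fell and 2 rose, and of 12 MHC class I genes 8 fell. Of 19 NF-kB genes 6 rose and 10 fell, and adjusted over the list alone 11 fell. Glycolysis genes rose for 15 of 17, and adjusted over the list alone for 16. Adjusted over the list alone the other counts of this paragraph were the same. In the same fit 6 of 7 neutrophil markers compared, all 3 mast cell, basophil and eosinophil markers compared and all 6 mitochondrial mRNAs rose.

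The next question was what 4 h of tunicamycin did in each kind. In M-BMDM with tunicamycin the genes of the PERK-ATF4 integrated stress response stood out. Chac1, a glutathione-degrading enzyme, was 92.1-fold higher than in untreated M-BMDM (59.5 to 151; 49.4 against 0.537 CPM, reads scaled to library size). The pseudokinase Trib3 was 54.9-fold higher (41.8 to 73.7), the amino acid transporter Slc7a5 15.2-fold (12.7 to 18.2), the stress transcription factor Ddit3, which encodes CHOP, 11.4-fold (10.5 to 12.4), the secreted factor Gdf15 9.93-fold (8.97 to 11) and Atf4 itself 3.84-fold (3.73 to 3.95). Of the list's 26 members 21 were at least 2-fold higher, and the median of 1.56 lay outside the -0.14 to 0.11 that held 95% of matched random lists. The ER chaperone and ERAD list (ER-associated degradation) had a median of 0.36 with 20 of 25 members above 0 and 4 at least 2-fold higher: Herpud1 5.22-fold (5.05 to 5.39), the main ER chaperone Hspa5 2.13-fold (2.11 to 2.16), Dnajb9 2.12-fold and Creld2 2.21-fold.

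Inflammatory genes were also higher in M-BMDM with tunicamycin. The NF-kB list had a median of 0.89 with 8 of 19 members at least 2-fold higher, among them the neutrophil-attracting chemokines Cxcl2 (8.45-fold, 7.74 to 9.24) and Cxcl1 (5.84-fold, 3.91 to 9.02), and the cytokine Tnf (2.42-fold, 2.28 to 2.57). Cd274 was 2.62-fold higher (2.48 to 2.76), the costimulatory ligand Tnfsf9 3.28-fold and the apoptosis gene Bbc3 2.87-fold. Lower genes included the anti-inflammatory cytokine Il10 (5.8-fold, 4.49 to 7.6), the stress gene Sesn1 (4.27-fold, 4.09 to 4.46), Nxpe5 (3.32-fold), Crip1 (3.21-fold), the tubulin Tubb2a (2.84-fold) and the coagulation factor subunit F13a1 (2.25-fold). The M-CSF macrophage list had a median of -0.47, the MHC class II and dendritic cell list -0.41, cholesterol synthesis -0.32, glycolysis -0.30 and pan-macrophage markers -0.31. In total 130 genes were at least 2-fold higher and 32 lower. Neutrophil markers had a median of 0.07 and mitochondrial mRNAs -0.24, inside the -0.36 to 0.11 of random lists.

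In GM-BMDM the same genes were higher by less. Chac1 was 9.36-fold higher (6.03 to 15.2), Trib3 5.38-fold (4.35 to 6.72), Ddit3 3.29-fold (2.99 to 3.63), the asparagine synthetase gene Asns 2.58-fold (2.32 to 2.87), Cxcl2 2.47-fold (2.14 to 2.86), Herpud1 1.65-fold and Hspa5 1.47-fold (1.45 to 1.49). The integrated stress response list had a median of 0.39, with 25 of 26 members above 0 and 4 at least 2-fold higher, against -0.07 to 0.06 for random lists. The ER chaperone list had a median of 0.10 with 21 of 25 members above 0. Lower genes were more numerous, 49 against 7 higher. They included the lectin receptor Asgr2 (5.59-fold, 4.67 to 6.74), the integrin Itgae (6.29-fold, 4.85 to 8.28), the kynurenine enzyme Kmo (3.93-fold, 3.38 to 4.57), the peptidase Dpp4 (3.78-fold), the lectin Cd209a (3.405-fold) and Ciita, the master regulator of MHC class II transcription (3.58-fold, 3.28 to 3.92).

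Of the 17 MHC class II and dendritic cell genes 16 were below 0 in GM-BMDM with tunicamycin, with a median of -0.51 against -0.10 to 0.07 for random lists, and H2-Eb1 was 2.16-fold lower. Markers of other cells were lower beside them. The 7 neutrophil markers had a median of -0.71, with Ngp 2.07-fold, S100a8 1.82-fold and S100a9 1.68-fold lower, the 3 mast cell markers -0.35 and the 6 mitochondrial mRNAs -0.41. All 20 mitosis genes (median -0.15) and 19 of 21 DNA replication genes (-0.21) were also below 0. The NF-kB list had a median of 0.20 with 1 of 19 members at least 2-fold higher.

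**Figure D1:**
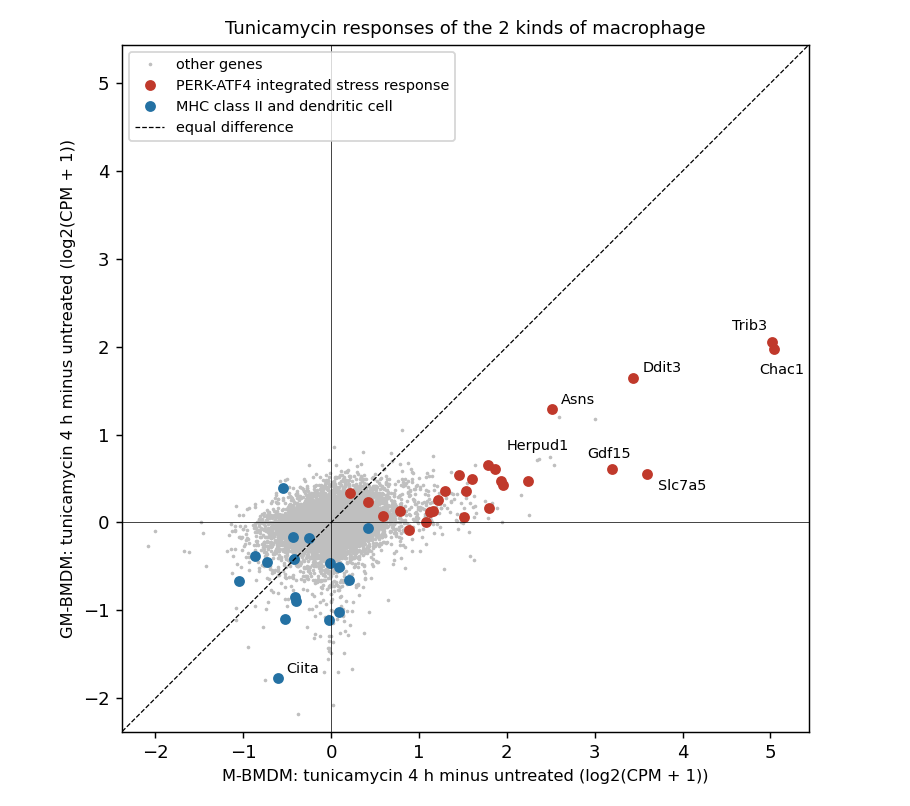
Each point is 1 gene, with 1 library per group. The log2 difference after 4 h of tunicamycin is on the horizontal axis for M-BMDM and on the vertical axis for GM-BMDM. Chac1 and Trib3 lie highest, 92.1-fold and 54.9-fold higher in M-BMDM and 9.36-fold and 5.38-fold higher in GM-BMDM.

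No gene passed the additive fit for a tunicamycin effect common to both kinds. edgeR's quasi-likelihood test called 0 genes, with 1103 at an unadjusted p under 0.05, and DESeq2 called 54 (21 higher and 33 lower). In that fit the difference between the 2 kinds' responses is the error. Adjusted over the list alone, with no correction across lists, edgeR's quasi-likelihood test called 20 of 26 integrated stress response genes higher (median log2 fold change 1.02). It called 9 of 19 NF-kB genes and 6 of 25 ER chaperone genes higher, and 10 of 17 MHC class II genes and 4 of 13 M2 polarization genes lower. Other lists had at most 2 calls in either direction, among them M1 polarization (2 of 10 higher) and mitochondrial mRNAs (2 of 6 lower). Across 11049 genes, which are not independent replicates, the 2 responses had a Pearson r of 0.33 and a Spearman rho of 0.31. Of the 7 genes at least 2-fold higher in GM-BMDM 6 were among the 130 in M-BMDM, where independent lists would share 0.0824, and 1 gene was lower in both.

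The responses were also subtracted gene by gene, GM minus M, without a test. The difference was at least 1 on the log2 scale for 23 genes and at most -1 for 152. The integrated stress response list had a median of -1.15, with 18 of 26 members at or below -1 and 25 below 0, against -0.11 to 0.12 for random lists. The largest differences were in Chac1 (-3.05), Slc7a5 (-3.04), Trib3 (-2.97), Gdf15 (-2.59) and the transcription factor Klf4 (-2.17). The NF-kB list had a median of -0.60, M1 polarization -0.61, MHC class II and dendritic cell genes -0.45, ER chaperones -0.26 and neutrophil markers -0.79.

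After tunicamycin the 2 kinds differed by at least 2-fold in 1388 genes higher and 864 lower in GM-BMDM. Chil3 (399-fold) and Arg1 (727-fold) were still higher in GM-BMDM, and Clec4a1 (83.1-fold) and Ifit3 (54.2-fold) still lower. Stress genes were lower in GM-BMDM at this point: Chac1 9.66-fold (8.4 to 11.2), Trib3 5.68-fold and Ddit3 4.38-fold. Tnf was 4.23-fold lower. The integrated stress response list had a median of -0.87 with 12 of 26 members at least 2-fold lower, the NF-kB list -1.36 with 11 of 19, and the ER chaperone list 0.03. Interferon-stimulated genes had a median of -2.89 and cholesterol synthesis genes 1.77. Neutrophil markers had a median of 3.59 and mitochondrial mRNAs 1.12.

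In the tumour part, the first question was what unstressed macrophage medium did to LLC cells. In both media Chac1 was higher than in untreated cells, 4.71-fold with GM medium (3.94 to 5.67) and 3.24-fold with M medium (2.69 to 3.93). The stromal surface protein Cd248 was 4.2-fold and 3.62-fold higher and the replication licensing factor Cdc6 2.25-fold and 2.12-fold. Among the genes lowest in both media were Plat, Ptgs2 and Cspg5. Plat, which encodes tissue plasminogen activator, was 11.3-fold lower with GM medium (8 to 16.5) and 17.4-fold with M medium (11.4 to 27.7). Ptgs2, the inducible prostaglandin synthase, was 7.44-fold (6.88 to 8.05) and 9-fold lower (8.27 to 9.8), and the proteoglycan Cspg5 15.3-fold and 14.5-fold. The collagen Col20a1 had 0 counts with GM medium, which is 44.6-fold lower with a floor of 3 counts put in place of the 0. It had 3 counts with M medium (44.9-fold lower, 15 to 221).

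DNA replication genes were higher in all 20 members compared in both media, with medians of 0.84 with GM medium and 0.75 with M medium (Rrm2 1.98-fold and 1.88-fold). The integrated stress response list had medians of 0.65 and 0.42, glycolysis 0.39 and 0.39, mitosis 0.30 and 0.29, and hypoxia 0.30 and 0.21. The NF-kB list had medians of -0.72 and -1.01, with 5 and 7 of 13 members at least 2-fold lower, among them the monocyte chemokine Ccl2 (2.07-fold and 2.64-fold), the cytokine Lif (2.89-fold and 5.47-fold) and Cxcl1 (2.49-fold with M medium). Lysosome and autophagy genes had medians of -0.62 and -0.23 with 17 of 18 members below 0 in each, and the sialidase Neu1 was 3.4-fold and 2.23-fold lower. Hspa5 was 1.18-fold higher with GM medium, and the ER chaperone list had medians of 0.10 with GM medium, inside the -0.10 to 0.20 of random lists, and 0.18 with M medium, above their -0.10 to 0.16. In total 116 genes were higher and 216 lower with GM medium, and 56 higher and 157 lower with M medium, of 11190 compared.

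The fit over all 5 LLC libraries set the 4 media together against the untreated library, which is assumed to vary like the others. This contrast averages stressed and unstressed media, so it holds part of the effect of stressed medium described further on. edgeR's quasi-likelihood test called 2781 genes higher and 2450 lower, and DESeq2 called 2037 genes, all of them among these. Genes of lowest p that fell included Ptgs2 (log2 fold change -2.38 ± 0.06 SE), the phosphatase Dusp1 (-2.28 ± 0.09), the heat shock protein Hspa4l (-1.70 ± 0.06) and Flrt2 (-1.67 ± 0.06). Those that rose included the lactate transporter Slc16a3 (1.11 ± 0.07), the amino acid enzyme Bcat1 (1.09), the ER oxidase Ero1l (1.07) and the glycolytic enzymes Tpi1 (0.96) and Ldha (0.89). The adjusted p was 5.8e-314 for Ptgs2 and 1.7e-57 for Slc16a3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

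All 20 DNA replication genes rose in this fit, as did 23 of 27 integrated stress response genes with 1 that fell, 23 of 25 ER chaperone genes (24 adjusted over the list alone) and 14 of 20 mitosis genes with 1 that fell (15 and 1 adjusted over the list alone). Of 17 glycolysis genes 11 rose and 2 fell (11 and 3 adjusted over the list alone). NF-kB genes fell for 9 of 13, lysosome genes for 16 of 18 and matrix genes for 8 of 13 with 3 that rose (8 and 4 adjusted over the list alone). The 2 unstressed media had differences from the untreated library that correlated across genes with r of 0.87 and rho of 0.85. Unchanged libraries set against that shared library gave a simulated r of 0.50. The covariance was 0.1396 against a simulated 0.0105. Of 116 and 56 higher genes 37 were shared (0.581 for independent lists), and of 216 and 157 lower genes 118 (3.03). Part of the excess may come from the shared untreated library.

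The main question of the tumour part was whether medium from stressed macrophages differed in its effect from unstressed medium. Hspa5 was 2.21-fold higher in LLC cells in stressed GM medium than in unstressed GM medium (2.17 to 2.25) and 2.41-fold higher for M medium (2.37 to 2.45). The actin-binding protein Avil was 20.96-fold higher with GM medium (16.5 to 27) and 10.4-fold with M medium (8.83 to 12.4). The carbonic anhydrase Car6 was 23.3-fold (15.5 to 36.6) and 21.05-fold higher (14.5 to 31.7). The iron-carrier protein Lcn2 was 15-fold (10.1 to 23.3) and 6.97-fold higher (4.58 to 11). The stress transcription factor Atf3 was 5.75-fold higher with M medium, and Ppp1r15a, a phosphatase subunit that restores translation after stress, 2.66-fold and 3.33-fold. In total 44 genes were higher and 14 lower with GM medium, and 46 higher and 16 lower with M medium.

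All 25 ER chaperone and ERAD genes were above 0 in both comparisons, with medians of 0.36 with GM medium (random lists -0.06 to 0.09) and 0.52 with M medium (-0.04 to 0.12). Hyou1 was 1.87-fold and 1.98-fold higher and Sdf2l1 1.78-fold and 2.04-fold. The integrated stress response list had medians of -0.01 and 0.08, inside the ranges of random lists. Its members went both ways, and in the fit described further on 10 rose and 5 fell. Trib3 was 1.04-fold higher with GM medium and 1.01-fold lower with M medium. Ddit3 stood at 30.8 and 40.87 CPM in unstressed and stressed GM medium, and at 32.51 and 46.54 in unstressed and stressed M medium. The NF-kB list had medians of 0.44 and 0.25, with 4 and 2 of 13 members at least 2-fold higher. Ptgs2 was 2.33-fold and 2.62-fold higher, Cxcl2 4.09-fold and 2.29-fold, Cxcl1 3.06-fold and 1.26-fold, and the neutrophil chemokine Cxcl5 4.68-fold with GM medium (2.97 to 7.68). Cxcl5 was not higher with stressed M medium, at low levels of 0.7097 against 1.161 CPM. Ccl2 was 1.37-fold higher with GM medium (1.285 to 1.46) and stood at 81.49 against 83.03 CPM with M medium. Cholesterol synthesis had medians of 0.39 and 0.21, glycolysis 0.23 and 0.22, hypoxia 0.21 and 0.20, NRF2 genes 0.22 and 0.17, heat shock 0.15 and 0.31, and fibroblast markers -0.63 and -0.57. Lower genes included the Notch target Hes1 (3.32-fold) and the peptidase Mme (2.24-fold) with GM medium, and Coro6 (5.02-fold) and Cryl1 (2.98-fold) with M medium.

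**Figure D2:**
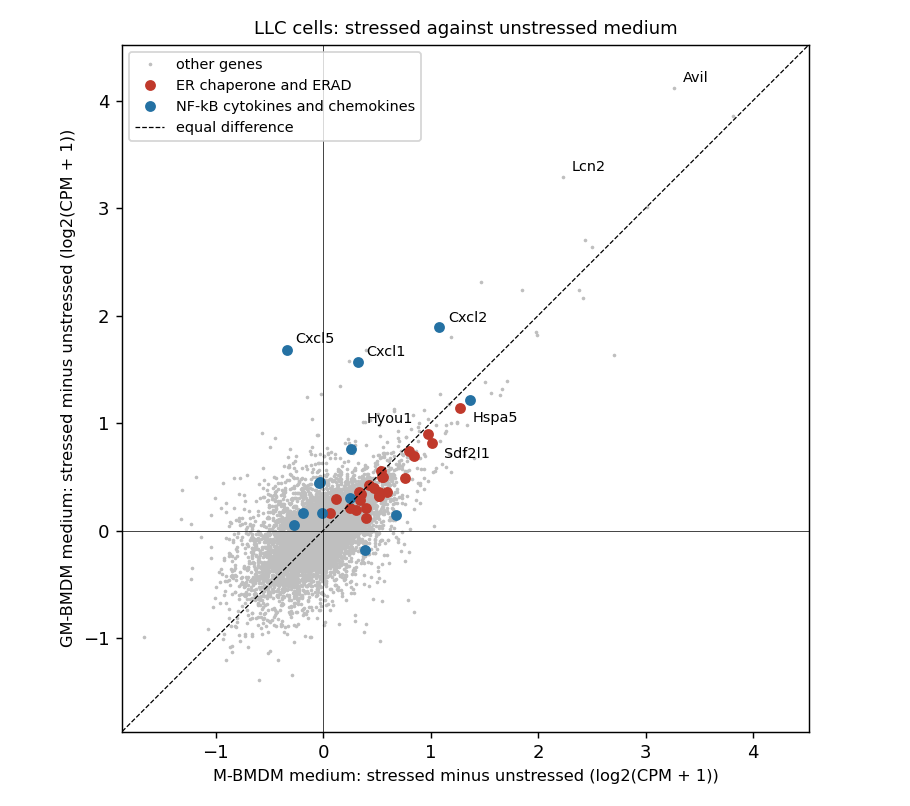
Each point is 1 gene in LLC cells, with 1 library per group. The log2 difference between stressed and unstressed medium is on the horizontal axis for M medium and on the vertical axis for GM medium. The 2 axes correlate with an r of 0.62, with Avil and Car6 far out on both and Cxcl5 4.68-fold higher with GM medium.

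Cd74, the MHC class II invariant chain, was 6.7-fold higher with stressed GM medium, at 10.5 against 1.56 CPM. With stressed M medium it stood at 6.45 against 0.387 CPM. Of macrophage markers measured beside it, the leukocyte genes Ptprc and Tyrobp had 0 counts in all 5 libraries, which allows up to 0.177 to 0.198 CPM, and the lysozyme gene Lyz2 lay between 2.73 and 5.01 CPM. Cd14 stood at 16.8 CPM in untreated cells, at 10.92 and 15.93 in unstressed and stressed GM medium, and at 12.97 and 14.02 in unstressed and stressed M medium. The 3 pan-macrophage markers compared had medians of 0.49 and 0.03.

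Across 11190 genes the 2 responses to stressed medium, which share no library, had a Pearson r of 0.62 and a Spearman rho of 0.57. Of 44 and 46 higher genes 27 were shared, where independent lists would share 0.181. None of the 14 and 16 lower genes was shared (0 genes, with 0.02 for independent lists).

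In the additive fit, edgeR's quasi-likelihood test called 1395 genes higher and 1216 lower in stressed medium, averaged over the 2 kinds. DESeq2 called 481 genes, all among these 2611. A call need not hold in each kind of medium. Mmp3 was called higher (log2 fold change 0.33), though with M medium it was lower in stressed medium, at 11.77 against 16.45 CPM. Genes of lowest p that rose were Avil (log2 fold change 3.80 ± 0.10 SE), Car6 (4.46 ± 0.17), Hspa5 (1.21 ± 0.05), Ppp1r15a (1.57 ± 0.07), Atf3 (2.45 ± 0.13) and Ptgs2 (1.30 ± 0.07). Their adjusted p-values ran from 2.2e-272 for Avil to 1.5e-75 for Ptgs2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Lcn2 (3.42) and Cd74 (3.15) rose as well. DESeq2 gave no adjusted p to Car6, Atf3, Lcn2 and Cd74, whose log2 fold changes there were 4.47, 2.46, 3.37 and 3.30. Genes that fell with lowest p were the corepressor Tle2 (-1.01), Mme (-1.01), the collagens Col3a1 (-0.72) and Col6a1 (-0.68), Igfbp7 (-0.73) and Sned1 (-0.67). Without the term for the kind of macrophage the fit called 867 genes.

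ER chaperone genes rose for 24 of 25 in this fit. Cholesterol synthesis genes rose for 14 of 23 (15 adjusted over the list alone), glycolysis for 10 of 17 with 1 that fell (11 and 1 adjusted over the list alone), hypoxia for 7 of 12, NF-kB for 7 of 13, NRF2 for 8 of 14 with 1 that fell, and heat shock for 5 of 8 (6 adjusted over the list alone). Of 27 integrated stress response genes 10 rose and 5 fell (11 and 8 adjusted over the list alone). Mitosis genes fell for 7 of 20 (8 adjusted over the list alone), matrix genes for 6 of 13 with 2 that rose (6 and 3 adjusted over the list alone) and fibroblast markers for 3 of 5. The 2 epithelial markers compared, Krt8 (-0.19) and Krt18 (-0.34), both fell. Of other lists, lysosome genes rose for 5 of 18 with 1 that fell, DNA replication genes for 4 of 20, matrix proteases for 3 of 8 with 2 that fell, M1 polarization genes for 2 of 6, and secreted danger signals for 3 of 7 with 2 that fell (4 and 2 adjusted over the list alone). Of 15 p53 and apoptosis genes 3 rose and 3 fell (5 and 3 adjusted over the list alone), and of 12 MHC class I genes 1 rose and 1 fell (1 and 3). Lists named in this paragraph without a second count had the same one when adjusted over the list alone.

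The last question was whether GM medium and M medium differed in their effect on LLC cells. In stressed media, LLC cells in GM medium held more RNA of the complement component C3 (7.06-fold, 6.08 to 8.24), Cxcl5 (9.85-fold, 5.42 to 19.6), the collagenase Mmp13 (4.51-fold), the stromelysin Mmp3 (3.73-fold), the chemokine Ccl7 (3.49-fold), Cxcl1 (2.33-fold) and Lcn2 (2.26-fold) than in M medium. The acute-phase gene Saa3 was 16.5-fold higher (6.13 to 62.5). Genes lower in stressed GM medium included Magohb (2.3-fold), the receptor Notch1 (2.27-fold) and Agt, the angiotensin precursor (2.4-fold). In unstressed media, GM medium was higher for Olfml3 (4.33-fold), the collagens Col7a1 (3.67-fold), Col8a1 (2.86-fold) and Col12a1 (2.48-fold) and the urea-cycle enzyme Ass1 (3.32-fold). It was lower for the acetylcholine receptor subunit Chrnd (3.67-fold), Agt (2.85-fold) and Avil (2.14-fold). In stressed media 23 genes were higher and 6 lower with GM medium, and in unstressed media 14 and 7.

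The NF-kB list was higher with GM medium in both comparisons, with medians of 0.19 in stressed and 0.21 in unstressed media, and so were matrix proteases (0.32 and 0.32). The lysosome list was lower (-0.13 and -0.30), as was cholesterol synthesis (-0.12 and -0.18). The ER chaperone list had a median of -0.11 in stressed media with 23 of 25 members below 0. In the difference of the 2 responses to stressed medium, GM minus M, the NF-kB list had a median of 0.36 and the ER chaperone list -0.06, inside the -0.09 to 0.02 of random lists. That difference was at least 1 for 35 genes and at most -1 for 14. It was 2.02 for Cxcl5, 1.25 for Cxcl1, 1.18 for Mmp13, 1.14 for C3 and 1.07 for Lcn2.

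The additive fit called 247 genes higher and 260 lower with GM medium by edgeR's quasi-likelihood test. DESeq2 called 37 genes, all among these 507, and without the term for tunicamycin the fit called 0 (289 at an unadjusted p under 0.05). Genes of lowest p that rose were C3 (log2 fold change 2.28 ± 0.11 SE), Col7a1 (1.76 ± 0.11), Mmp13 (1.65 ± 0.16), Mmp3 (1.23 ± 0.12), Skil (0.79) and Fstl1 (0.78). DESeq2 gave no adjusted p to C3, Col7a1, Mmp13 and Mmp3, whose log2 fold changes there were 2.23, 1.76, 1.56 and 1.21. Genes that fell with lowest p were the ectoenzyme Cd38 (-0.86), Sned1 (-0.82), Uap1l1 (-0.64), the lysosomal glycoprotein Gpnmb (-0.59), Tns1 (-0.58) and the transferrin receptor Tfrc (-0.54). Of these, Tfrc did not pass DESeq2. The adjusted p was 1e-94 for C3 and 3.5e-40 for Sned1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Integrated stress response genes rose for 12 of 27 (16 adjusted over the list alone), NF-kB genes for 7 of 13 (8 adjusted over the list alone) and matrix proteases for 4 of 8 (6 adjusted over the list alone). Many of these were given no adjusted p by DESeq2. They were Chac1, Cebpb and Fgf21 of the stress response list, Cxcl1, Cxcl2, Cxcl5, Ccl7 and Nfkbiz of the NF-kB list, and the proteases Mmp3, Mmp9 and Mmp13. The other stress response genes that rose were given one. Their edgeR folds were small, from 1.13 (Shmt2) to 1.22 (Pck2), and the list's median log2 fold change was 0.17. DESeq2 called only 14 genes higher with GM medium in all. Lysosome genes fell for 12 of 18 and cholesterol synthesis genes for 4 of 23, and both counts were the same when adjusted over the list alone. M1 polarization genes rose for 1 of 6 (3 adjusted over the list alone), and NRF2 genes fell for 2 of 14 (2 higher and 4 lower adjusted over the list alone). None of the 25 ER chaperone genes passed, a count of 0 also when adjusted over the list alone.

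**Figure D3:**
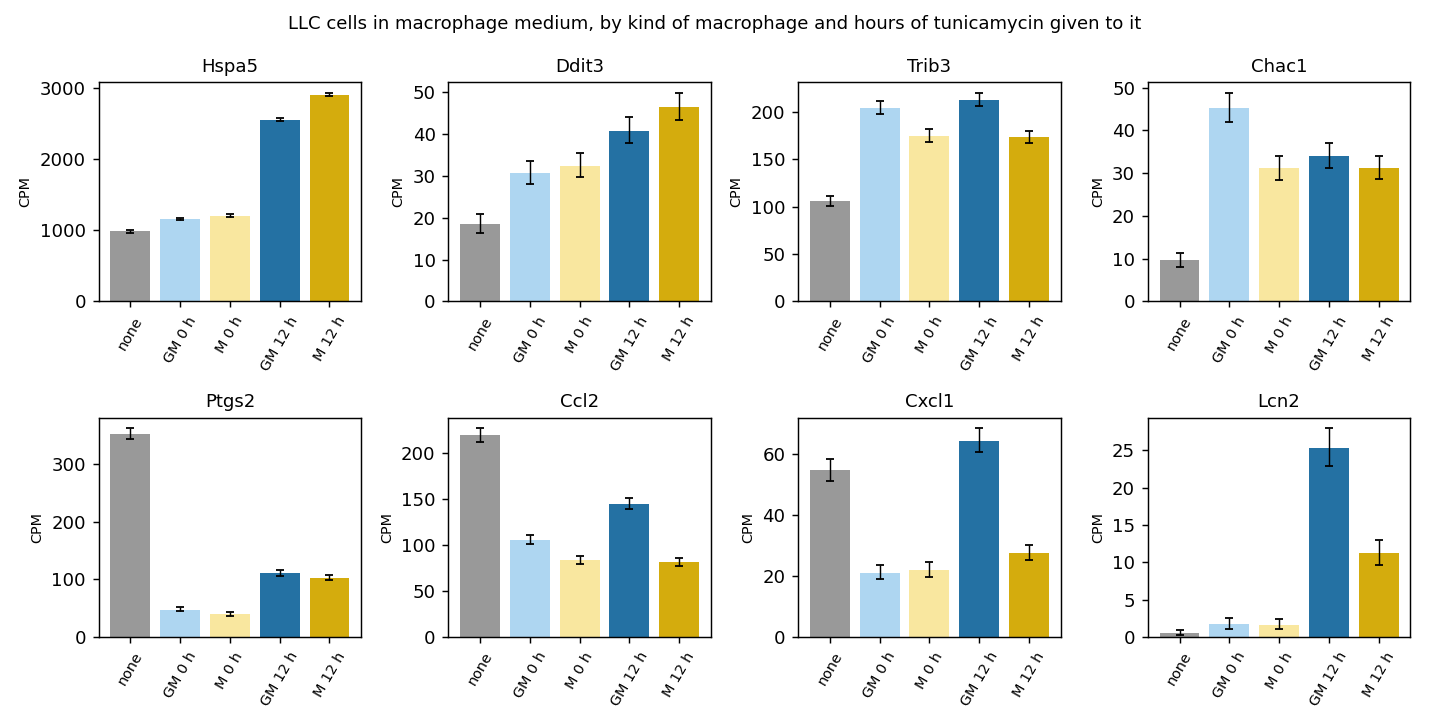
Bars give CPM of named genes in each of the 5 LLC libraries, 1 library per group, with 95% counting intervals. Hspa5 stood at 985 CPM in untreated cells, 1158 and 1206 in unstressed GM and M medium, and 2555 and 2907 in stressed GM and M medium.

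Positions of the genes that lead these comparisons are given in mouse build GRCm38. Chac1 (ENSMUSG00000027313) lies on chromosome 2 at 119351229 to 119354381, Trib3 (ENSMUSG00000032715) on chromosome 2 at 152337422 to 152344032 and Hspa5 (ENSMUSG00000026864) on chromosome 2 at 34771970 to 34777547. Ddit3 (ENSMUSG00000025408) lies on chromosome 10 at 127290774 to 127296288 and Avil (ENSMUSG00000025432) on chromosome 10 at 127000709 to 127020994. Car6 (ENSMUSG00000028972) lies on chromosome 4 at 150187015 to 150201332, C3 (ENSMUSG00000024164) on chromosome 17 at 57203970 to 57228136 and Ptgs2 (ENSMUSG00000032487) on chromosome 1 at 150100031 to 150108227. Chil3 (ENSMUSG00000040809) lies on chromosome 3 at 106147554 to 106167564, Cxcl5 (ENSMUSG00000029371) on chromosome 5 at 90759360 to 90761624 and Ciita (ENSMUSG00000022504) on chromosome 16 at 10480059 to 10528418. Avil overlaps Tsfm on the opposite strand over 9423 bases and Ciita overlaps Dexi over 25888 bases, so reads of these pairs could not be told apart without strand information. Itgae, Kmo, Slc7a5 and Ddit3 overlap other genes as well, and their values are uncertain to that extent.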

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

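All tests of explanations in this part were chosen after the result was seen. Among genes that the naming rule picked in both comparisons of a pair, 5 differed in opposite directions with counting intervals that left out 0, and the difference was not tested in any of them. After tunicamycin the cell-cycle inhibitor Cdkn1a differed by -0.19 on the log2 scale in GM-BMDM and by 0.92 in M-BMDM, a difference of -1.11. Fn1 differed by -0.49 and 0.48, a difference of -0.98. The neutrophil granule gene Ngp differed by -1.02 and 0.43, a difference of -1.45. Both genes were low in M-BMDM, with 123 reads after tunicamycin against 67 for Fn1 and 30 against 10 for Ngp. In LLC cells, stressed against unstressed medium, the interferon signalling factor Irf9 differed by 0.44 with GM medium and -0.42 with M medium, a difference of 0.86. The stromelysin Mmp3 differed by 0.86 and -0.45, a difference of 1.31.

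The integrated stress response genes differed more after tunicamycin in M-BMDM than in GM-BMDM. A higher starting level in GM-BMDM that left both kinds at the same end point is argued against, since the list's median after tunicamycin was -0.87 (GM minus M), below the -0.31 to 0.23 of matched random lists. A different time course in the 2 kinds, a different uptake of the drug and a property of the kind of macrophage itself stay open and untested. So does a lower share of responding cells in GM cultures, which held more RNA of most neutrophil and mast cell markers compared.

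In stressed media the ER chaperone list was higher in LLC cells with both media, and the NF-kB list, with its chemokines, had a median of 0.44 with GM medium and 0.25 with M medium, where 6 of 13 members were below 0. Tunicamycin left in the medium may account for the chaperone part, and it cannot be told apart from a factor made by the macrophages: the lower of the 2 list medians was 0.36 against -0.06 to 0.09, and both explanations give higher values in both media. The macrophages were washed before the medium was added, and no medium with tunicamycin but without macrophages was among the libraries, which keeps this open. More tunicamycin in GM medium as the whole source of the larger chemokine difference there would put the ER chaperones higher in stressed GM than in stressed M medium. Their median was -0.11, below the -0.05 to 0.03 of random lists, but it was already -0.05 in unstressed media. The difference of their responses, -0.06, lay inside the -0.09 to 0.02 of random lists. A larger chaperone response with GM medium was thus not seen. The bound of this test was rewritten after its values were seen, so the explanation stays open.

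Cd74 was higher in LLC cells in stressed media of both kinds. Macrophage cells or RNA carried over with the medium are argued against: the macrophage markers gained at most 1.68% of the CPM that the gain of Cd74 would need (5.82 CPM where 347 CPM would be needed with GM medium, and 1.25 where 420 would be needed with M medium). A response of the LLC cells themselves stays open as a hypothesis.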

How the results depend on the processing

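The tests with assumed dispersions, the differences of responses and the fits without the untreated library were chosen after seeing the data. Each group held 1 library, so no pairing of replicates was possible beyond the term for kind in the additive fits. Leaving out a library other than the untreated LLC one left 0 residual degrees of freedom. Without the untreated LLC library, 2622 genes were called for stressed medium, 2593 of them among the 2611, and 508 for the kind of medium, 504 of them among the 507. Alternatives planned for normalized values alone (limma, quantile normalization, a pseudocount in the fits) were not run, since counts were deposited. No named gene changed its direction under any alternative run. No list outside the range of random lists moved outside it on the other side. Part of this was fixed in advance, since a pseudocount cannot turn a gene's sign and unmatched random lists leave a list's median as it was. The balance of higher and lower calls turned in some fits, as the splits here show. DESeq2 size factors left all 12 totals of library pairs and response differences and all 5 fits within 1.5 times. Depth limits low genes, and the choice of pseudocount and filter acts on them most by construction.

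With a mean of at least 5 CPM, which compares fewer genes, the genes at least 2-fold apart numbered 218 (unstressed GM medium against untreated), 129 (unstressed M medium against untreated), 32 (stressed against unstressed GM medium), 29 (the same for M medium), 16 (GM against M medium, stressed), 12 (unstressed) and 34 (tunicamycin in GM-BMDM). With a pseudocount of 0.1, which shrinks low genes less, they numbered 562, 399, 177, 184, 107, 108 and 94 in that order, 291 for tunicamycin in M-BMDM, and 343 (BMDM) and 184 (LLC) for the differences of responses. Counting intervals beyond 2-fold left 191, 110, 34, 37, 18 and 9 for the 6 LLC comparisons in that order. The correlations were 0.69 for stressed medium, 0.37 for tunicamycin and 0.89 for medium against untreated with a mean of at least 5 CPM, and 0.58, 0.30 and 0.85 with a pseudocount of 0.1.

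For the common tunicamycin effect in BMDM, 0 genes with edgeR became 54 with DESeq2 (21 higher and 33 lower), 101 without a filter (48 and 53), 579 with an assumed dispersion of 0.01 (293 and 286) and 44 with 0.04 (28 and 16). For the BMDM kinds 5568 became 3349 with 0.04 (1896 and 1453), and 6299 with 0.01 (3086 higher and 3213 lower, against 2803 and 2765). For stressed medium 2611 became 481 with DESeq2 (317 higher and 164 lower), 867 with that factor alone (519 and 348), 488 with 0.01 (219 and 269) and 30 with 0.04 (29 and 1). For the kind of medium 507 became 37 with DESeq2 (14 and 23), 0 with that factor alone, 67 with 0.01 (43 and 24) and 9 with 0.04 (7 and 2), against 247 and 260. For any medium 5231 became 2037 with DESeq2, 1617 with that factor alone, 2233 with 0.01 (1065 higher and 1168 lower, against 2781 and 2450) and 271 with 0.04 (69 and 202). DESeq2 gave an adjusted p to 7285 genes for stressed medium and to 4031 for the kind of medium, fewer than edgeR tested. It was run with its default filter on the mean count, which withholds an adjusted p from genes below a cut-off. A gene without one is thus not a gene that failed its test. The dispersions assumed are larger than the LLC estimate of 0.001835, and fits with a factor left out carry its effect as error. What else separates the tools was not tested.

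Among named genes in the fits, 519 of 743 kept their call with DESeq2, 161 lost it and 63 LLC ones were given no adjusted p there (all 63 in the same direction). The numbers kept and lost were 461 and 282 with the factor alone, 731 and 12 without a filter, 737 and 6 with DESeq2 size factors, 523 and 220 with 0.01, and 295 and 448 with 0.04. In pairs of libraries 1060 values stayed within their counting interval with DESeq2 size factors and 117 moved beyond it, none of them reversed. With unmatched random lists 231 list results stayed on their side of the range, 17 moved outside and 6 inside.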

Other observations

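Levels of several genes in LLC cells differed both from untreated cells and between media. Ptgs2 stood at 352 CPM in untreated cells, 47.4 and 39.2 in unstressed GM and M medium, and 110.5 and 102.5 in stressed GM and M medium. Cxcl1 stood at 54.8, 21.1 and 22 CPM in untreated cells and the 2 unstressed media, and at 64.55 and 27.7 in stressed GM and M medium. Chac1 stood at 9.62 CPM in untreated cells and between 31.2 and 45.3 in all 4 media. C3 stood at 39.8 and 82.7 CPM in unstressed and stressed GM medium, and at 12.6 and 11.7 in M medium, against 13.6 in untreated cells.

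The remaining lists had these values in LLC cells. Interferon-stimulated genes had medians of 0.06 with stressed GM medium and -0.30 with stressed M medium against the unstressed media, MHC class I 0.01 and -0.15, p53 genes 0.03 and 0.10, and mitochondrial mRNAs 0.02 and -0.02. In unstressed GM and M medium against untreated cells, checkpoint ligands had medians of -0.06 and -0.14, M2 polarization genes -0.18 and -0.12, M-CSF macrophage genes -0.50 and -0.34, and secreted danger signals 0.36 and 0.19. The erythroid list had 1 member compared in LLC cells, Alas2, at 11 counts in untreated cells and 25 and 29 in unstressed GM and M medium. No lymphocyte or mast cell marker passed the minimum level in LLC cells. S100a9 and Tnf had 0 counts in all 5 LLC libraries, and the growth factor Csf2 had between 2 and 18.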
